A study of Homo sapiens with 6 samples.

How the data were processed

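PAR-CLIP of ALKBH5 in wild-type and RBM33-knockout HEK293 cells and of RBM33 in wild-type HEK293 cells was used, 6 samples in 3 groups. Groups came from the sample titles. The deposited lists of both wild-type groups are named for control siRNA while the labels say wild type. The labels were followed, and whether those cells also received siRNA, which the knockout list does not name, is not known here. Samples of the UM-SCC-1 line that the design text names were not analysed here. For each group the authors deposited 1 list of T-to-C clusters with both replicates merged, with 6 columns (chromosome, start, end, name, score and strand), so no file holds a value per replicate. The deposited score of a cluster has no stated definition. Its values look like a sum of T-to-C percentages over the positions of a cluster, which was not tested. No column is described as read depth, and the score was used only to rank or filter clusters within a list. The submitters' processing notes name cutadapt 1.18, Bowtie2 2.4.5, STAR 2.7.9a, HOMER 4.9 and the hg38 genome. The cluster caller, its filters and the annotation are not given in the sources used here. A place enters a list only if its RNA is abundant enough for reads, and no measure of RNA abundance was used here.

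Clusters were assigned to genes of GENCODE release 44 (basic transcripts, same strand) by the largest exon overlap and otherwise by intron. Classes were ranked as coding sequence, 3' UTR, 5' UTR, noncoding exon and intron, with small RNA and mitochondrial clusters set apart. Coordinates are 1-based on GRCh38. Clusters were called shared when they overlapped by at least 1 nt on the same strand, and a wild-type cluster without such overlap was called lost. Expected overlap came from 100 shuffles that moved each cluster to a random place of the same gene and class. Shares have exact binomial (Clopper-Pearson) intervals and differences of shares Newcombe intervals. Odds ratios have Woolf intervals, pooled ones are Mantel-Haenszel values, and a bootstrap over genes (1000 draws) gave 0.19 to 0.21 for the odds ratio of cluster loss. Ratios of covered shares have intervals from as many draws. No p-value between conditions was computed, since each group is 1 list. Distance to the stop codon was measured on the representative transcript with a window of 200 nt. DRACH matches were counted with an extension of 20 nt against 20 shuffles.

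The 24 fixed gene lists were compared by clusters per gene with 0.5 added, and each list with at least 5 members that had an ALKBH5 cluster was ranked among 10000 random lists matched on clusters per gene. Names of lists are approximate, as the long noncoding list includes NORAD and GAS5. Genes named were RBM33, ALKBH5 and DDIT4, the 10 genes with the largest net number of wild-type clusters lost minus knockout clusters gained and the 10 with the smallest. The rule added the 10 genes with the most ALKBH5 clusters overlapped by RBM33, the 5 with the most RBM33 clusters and no ALKBH5 cluster, up to 4 members per fixed list, and the 3 clusters of highest score per list. Other list members were named after their values were seen. Y-linked genes were left out, and some items that the rule names are not reported here. The groups, the comparisons, the fixed lists, the naming rule and most other processing choices tried were set before the data were examined. The comparison by exons, the odds ratio within genes, the motif density by exon, the ratio of summed clusters, the fixed lists at equal length the overlap of fixed lists with RBM33 against random lists, the small RNA share at equal length and the clusters found in 1 ALKBH5 list alone were added afterwards.

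The odds ratio of loss was tested on simulated data with 35306 clusters and 20 runs each. With loss unrelated to RBM33 its median was 1.00, with a true value of 2 it was 2.02, and with a true value of 0.5 it was 0.50. In a simulation where places differed only in how readily they are detected, with no effect of the knockout, the median was 0.37, and the mirror comparison gave 0.37. Its settings were not fitted to the deposited lists, and its model makes both values equal by design. Of 400 random lists of 20 genes, 6.25% fell outside the middle 95% by the median. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, matplotlib 3.10.9 and blastn 2.17.0.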

Results

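The places on RNA contacted by ALKBH5, the demethylase that removes m6A (N6-methyladenosine) from RNA, and by the RNA-binding protein RBM33 were mapped by PAR-CLIP in HEK293 cells, a human embryonic kidney line. In PAR-CLIP, cells take up 4-thiouridine (200 uM for 14 h here), UV light (0.15 J per cm2) joins protein to RNA, and the joined bases read as T-to-C changes. The groups were ALKBH5 in wild-type cells, ALKBH5 in RBM33-knockout cells and RBM33 in wild-type cells. Each group had 2 libraries, which the authors merged into 1 list of clusters, so no spread between replicates is known. Intervals below are 95% intervals that cover counting error over clusters or genes only, and clusters of a gene are not independent. The wild-type ALKBH5 list held 35306 clusters over 4.81 Mb in 7991 genes, the knockout ALKBH5 list 30726 clusters over 4.33 Mb in 7334 genes, and the RBM33 list 14381 clusters over 1.80 Mb in 4782 genes. Read depth is unknown for all 3 lists. The median cluster was 124 nt wide in the wild-type ALKBH5 list, 128 nt in the knockout list and 113 nt in the RBM33 list.

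The first comparison asked how ALKBH5 contacts differ without RBM33. Net loss here is the number of wild-type clusters of a gene without a knockout counterpart minus the number of knockout clusters without a wild-type one, which can differ from the difference in clusters. The gene with the largest net loss was CENPF, a kinetochore protein (chromosome 1, 214603185 to 214664574), with 22 clusters in the wild-type list and 5 in the knockout list. ASPM, a spindle pole protein (chromosome 1, 197084121 to 197146694), had 19 and 5. The proliferation marker MKI67 (chromosome 10, 128096659 to 128126423) had 38 and 24, and DNA topoisomerase TOP2A (chromosome 17, 40388525 to 40417896) had 30 and 19. Of the 8899 genes with an ALKBH5 cluster in either list, 4403 had fewer in the knockout list, 2382 had more and 2114 had as many.

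Other genes with the largest net loss were TEX14, second by this measure and a protein of intercellular bridges (chromosome 17, 58556678 to 58692055), with 36 wild-type and 21 knockout clusters, the centriolar satellite gene PCM1 with 24 and 11, and the calcium release channel gene RYR2 with 27 and 16. BDP1, a subunit of the RNA polymerase III initiation factor, had 21 and 9, and the histone methyltransferase gene KMT2B had 35 and 24. The long noncoding gene ENSG00000280441, which lies over ribosomal RNA repeats on chromosome 21 (8380643 to 8454792), had 41 and 31. The sequence of ENSG00000280441 occurs in many copies. With each list limited by score to the length of the shortest, net losses were smaller: 17 became 7 for CENPF, 15 became 7 for TEX14, 14 became 9 for ASPM and 5 for MKI67, 13 became 2 for PCM1, 12 became 5 for RYR2 and 3 for BDP1, and 11 became 3 for TOP2A, 2 for KMT2B and -1, a net gain, for ENSG00000280441. This limit keeps 14381 clusters of each list, so net numbers shrink in part by construction. A smaller value alone does not show that a difference is fragile. The genes with the largest net gain included LRRC45, which encodes a centrosomal protein (chromosome 17, 82023305 to 82031151), with 1 wild-type and 16 knockout clusters. The ribosome assembly ATPase MDN1 had 49 and 59, the receptor phosphatase PTPRS 9 and 19, and the deubiquitinase USP24 31 and 40. NBEAL2 had 11 and 20 clusters, the mitochondrial myosin gene MYO19 13 and 21, the Mediator gene MED13 12 and 20, and the vesicle coat gene SEC31A 11 and 19. At equal length the net value was -4 for LRRC45 and USP24, -6 for PTPRS, -3 for NBEAL2 and 0 for SEC31A, so that the gain of SEC31A was not seen there, while MDN1 (-14), MYO19 (-6) and MED13 (-8) moved by less than 1.5 times. ALKBH5 clusters also lay on the RBM33 transcript itself in the knockout list, 13 clusters against 14 in the wild-type list. The ALKBH5 transcript had 10 wild-type and 12 knockout clusters, and DDIT4, an inhibitor of mTORC1, had 4 and 3.

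**Figure D1:**
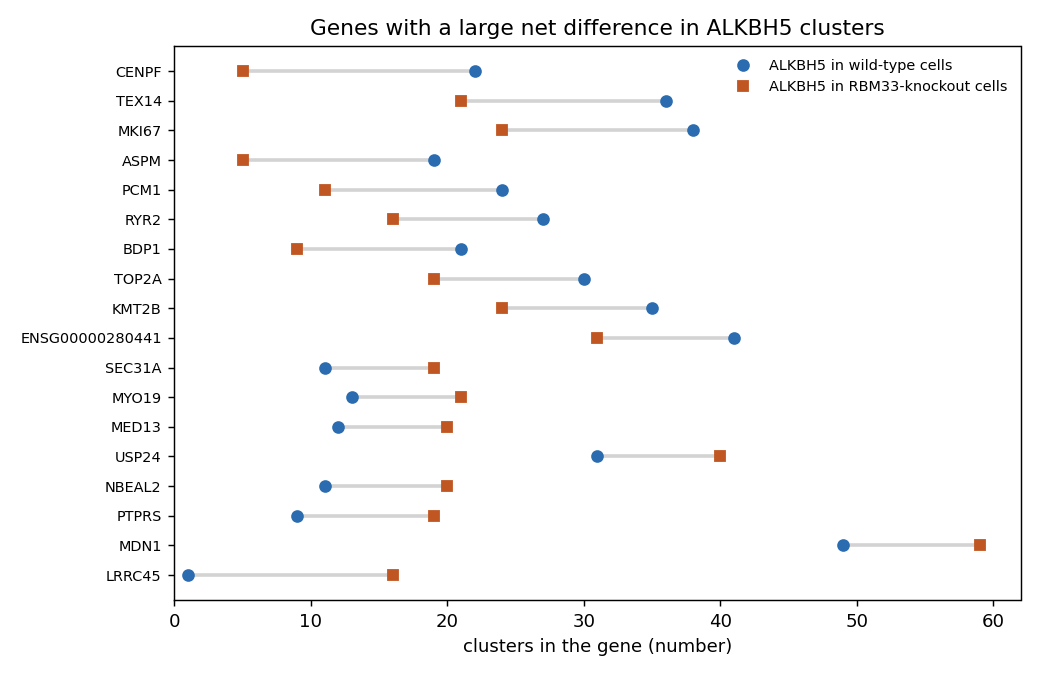
ALKBH5 clusters per gene (x axis, number) in the wild-type list (circles) and the knockout list (squares) for 18 of the genes with the largest net difference. CENPF goes from 22 to 5 clusters and LRRC45 from 1 to 16.

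Across the 24 fixed gene lists, 20 had enough members for a comparison with 10000 random lists of genes with similar numbers of clusters. The cell cycle and mitosis list had 193 wild-type and 132 knockout clusters. Of its members, 13 had fewer clusters in the knockout list, 3 had as many and 4 had more. Its median log2 ratio of knockout to wild-type clusters was -0.57, at percentile 0.22 of the random lists, and its log2 ratio of summed clusters was -0.55, at percentile 0.03. With lists of equal length the median stood at percentile 0.65. CENPE had 20 wild-type and 11 knockout clusters, BUB1 had 8 and 4, and FOXM1 had 8 and 4, while MYBL2 had 12 and 13, and CCND2 had 0 and 4. The SUMO pathway list stood at percentile 1.71 by its median log2 ratio of -0.74 but at 23.6 by its summed clusters, 72 and 57. RANBP2 had 10 and 5 clusters and SENP1 7 and 3, whereas SENP2 had 0 and 4. With 20 lists, 1 is expected outside the middle 95% by chance.

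The remaining lists stayed within the middle 95% of the random lists. The m6A writers, erasers and readers had 155 wild-type and 118 knockout clusters, at percentile 13.2 by the median and 2.77 by summed clusters. The methyltransferase subunits ZC3H13 and WTAP had 12 and 4 clusters and 8 and 3, the reader IGF2BP2 had 9 and 2, and METTL3 had 5 and 6. The ATF4 and unfolded protein response list had 84 and 63 clusters (percentile 9.35), and the oncogenes and described ALKBH5 targets had 45 and 29 (percentile 14.8). Within that last list, MYC had 6 and 5 clusters and the mitotic gene TACC3 had 11 and 8. The autophagy and mTOR list had 138 and 137 clusters, with TSC2 at 32 and 33 and MTOR at 29 and 29. Cytosolic ribosomal protein genes had 320 and 301 clusters, translation factor genes 299 and 267, and chromatin remodellers 463 and 401. SR protein genes had 161 and 137 clusters, hnRNP genes 251 and 223, mRNA export genes 174 and 157, and heat shock and chaperone genes 234 and 205. Glycolysis genes had 137 and 128 clusters, cholesterol synthesis genes 138 and 124, DNA damage and p53 target genes 111 and 98, and histone genes 59 and 59. The long noncoding RNAs had 55 and 43, with MALAT1 at 18 and 11 and NORAD at 5 and 1. The small structural RNAs had 13 and 14, and the mitochondrially encoded transcripts 20 and 20. Markers of other cell types were nearly absent: the wild-type list had 2 clusters in collagen and fibroblast genes, 2 in keratinocyte genes and 0 in blood cell genes. Of the 13 kidney line markers, only 4 had clusters, 22 in the wild-type list and 14 in the knockout list. Among them were VIM with 10 and 9 and NEFL with 6 and 2, while PAX2, PAX8 and LHX1 had 0 in both lists.

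**Figure D2:**
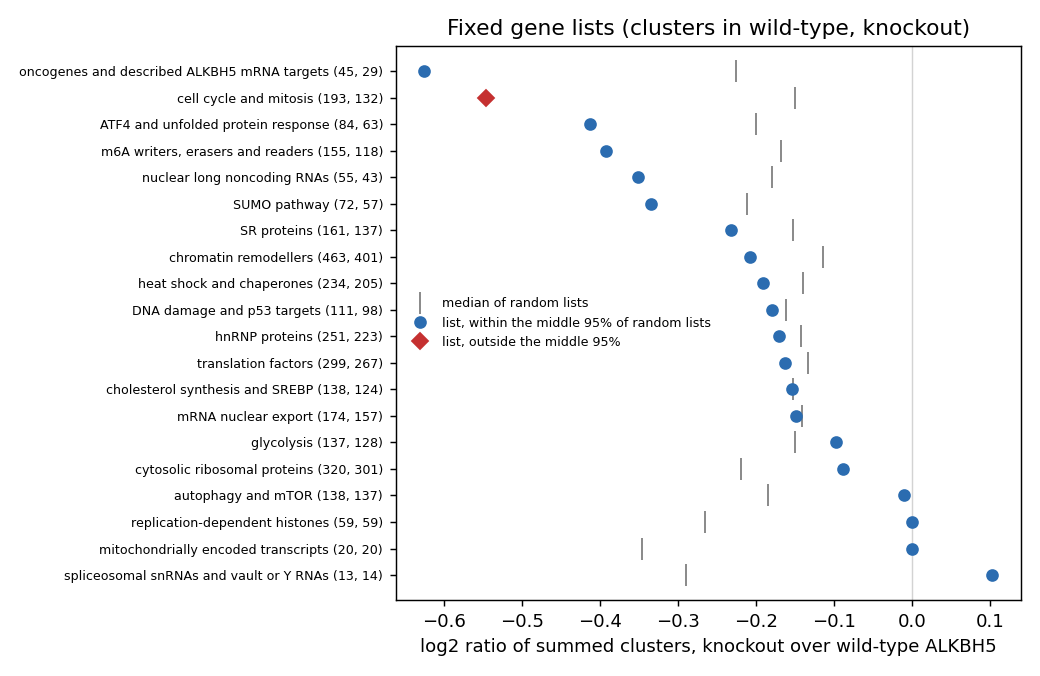
Log2 ratio of summed ALKBH5 clusters, knockout over wild-type (x axis), for the 20 fixed lists, with the median of matched random lists as ticks. The cell cycle and mitosis list, at -0.55, is the 1 list outside the middle 95% by this measure.

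At the level of places, 58.5% (57.9 to 59.0) of wild-type ALKBH5 clusters were overlapped by a knockout cluster on the same strand, against 32.1% when knockout clusters were moved at random within their gene and class. In the other direction 67.1% of knockout clusters were overlapped. Of the 7991 genes with wild-type clusters, 6426 (80.4%, 79.5 to 81.3) also had a knockout cluster, and clusters per gene correlated across 9046 genes (Pearson r 0.93, Spearman rho 0.75; genes are not independent replicates). Clusters followed exons. In internal exons, 59.7% of wild-type ALKBH5 clusters and 48.4% of RBM33 clusters had both ends within 12 nt of the exon edges, so overlap is in part a measure of which exons were hit, less so for RBM33. With exons as units, the lists shared 1.59 times (1.59 to 1.60) the number expected from independent draws within genes. This expectation takes all exons of a gene as equally likely, whatever their class or length. A shared preference for coding or longer exons can therefore raise the ratio.

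Coding sequence held most clusters in all 3 lists, 84.0% for wild-type ALKBH5, 85.1% for knockout ALKBH5 and 83.3% for RBM33. Clusters in 3' UTRs made up 6.17%, 5.18% and 4.43%. The wild-type share depended on the processing, at 11.8% with 3' UTR ranked before coding sequence and 10.3% in the upper part of the list by score. The knockout share was 0.99 points below the wild-type share, a difference of -0.99 points (-1.35 to -0.64). Of wild-type clusters, 54.1% in 3' UTRs and 40.6% in coding sequence had no knockout counterpart. In the other direction, 39.0% of knockout clusters in 3' UTRs and 32.7% in coding sequence had no wild-type counterpart. Small RNA clusters were about as many for RBM33 as for wild-type ALKBH5, 158 and 167, in lists of different length. Their share was 1.10% against 0.47%, a difference of 0.63 points (0.45 to 0.82), and with lists of equal length the difference was 0.19 points (-0.04 to 0.43), not apart from 0. Equal length keeps the whole RBM33 list but only the highest-scoring ALKBH5 clusters, among them 130 of the 167 in small RNA. In the upper part of each list by score, the share was 1.72% for RBM33 and 0.80% for wild-type ALKBH5, a difference of 0.93 points. Coding sequence of genes with clusters was covered to 24.8% by the wild-type ALKBH5 list and 3' UTR sequence to 3.53%. Within 200 nt of the stop codon, where m6A is known to be dense, lay 11.3% of wild-type ALKBH5 clusters (11.6% expected along the same transcripts), 10.7% of knockout clusters (11.5% expected) and 12.4% of RBM33 clusters (12.4% expected). The expected share is even along the transcript, although 3' UTRs held few clusters, so it cannot exclude a concentration near the stop codon. In last exons, the wild-type ALKBH5 list covered the first 200 nt of 3' UTR to 13.5%, above its 3.53% of all 3' UTR sequence. It covered the last 200 nt of coding sequence there to 20.7%, below its 24.8% of all coding sequence. The m6A consensus DRACH occurred in 95.3% of wild-type ALKBH5 clusters extended by 20 nt, 95.1% of knockout clusters and 94.8% of RBM33 clusters, against 92.9%, 93.2% and 92.0% of shuffled places. In coding exons with a cluster, DRACH matches per 100 nt were 1.13 times (1.11 to 1.14) those in exons without one in the same genes for wild-type ALKBH5, 1.08 times (1.07 to 1.10) for knockout ALKBH5 and 1.15 times (1.13 to 1.16) for RBM33.

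**Figure D3:**
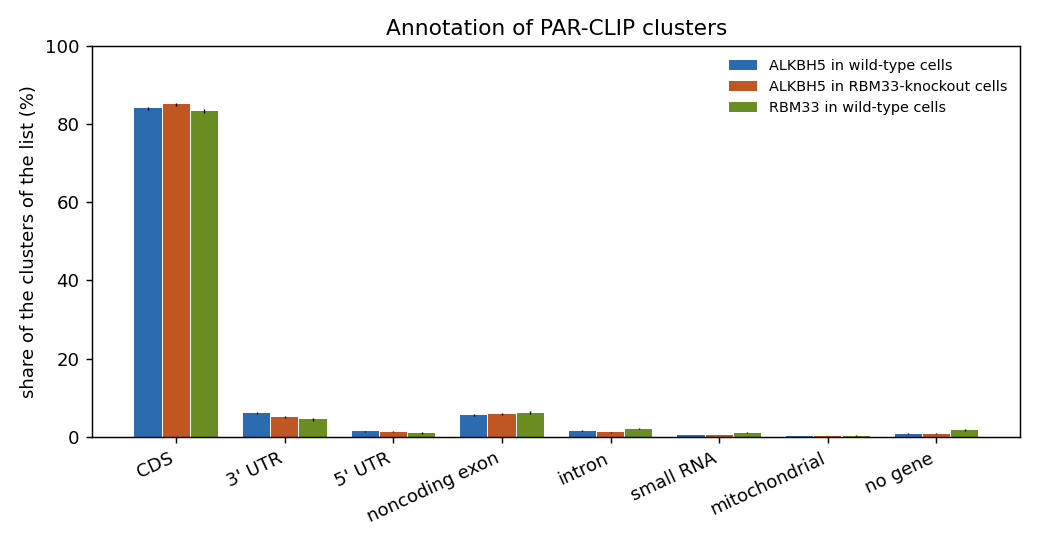
Share of clusters (y axis, percent of the list) by annotation class for the 3 lists, with exact binomial 95% intervals. Coding sequence holds 84.0%, 85.1% and 83.3% of clusters.

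The second comparison asked whether ALKBH5 and RBM33 are found on the same RNAs. HUWE1, a ubiquitin ligase (chromosome X, 53532096 to 53686752), had the most shared places: 43 of its 67 wild-type ALKBH5 clusters were overlapped by RBM33. The fatty acid synthase gene FASN (chromosome 17, 82078338 to 82098294) followed with 39 of 50, and UBR4, another ubiquitin ligase, had 34 of 76. The splicing genes SRRM2 and PRPF8 had 34 of 38 and 33 of 43, the nuclear pore gene TPR 33 of 45, and MKI67 33 of 38. The dynein heavy chain gene DYNC1H1 had 28 of 56, PRRC2C 27 of 42, and ENSG00000280441 37 of 41. RBM33 itself had 26 RBM33 clusters, and all 14 of its wild-type ALKBH5 clusters were overlapped. DDIT4 had 0 RBM33 clusters. Of the 20 fixed lists, 12 had a larger share of ALKBH5 clusters overlapped by RBM33 than the middle 95% of random lists matched on wild-type clusters per gene, in a comparison chosen after the data were seen. The share was 100% of 20 clusters for mitochondrially encoded transcripts, 92.3% of 13 for small structural RNAs, 70.0% for ribosomal protein genes, 69.6% for SR protein genes, 66.1% for histone genes, 64.5% for hnRNP genes, 63.6% for long noncoding RNAs, 62.4% for heat shock and chaperone genes, 61.2% for translation factor genes, 54.7% for glycolysis genes, 54.4% for cell cycle and mitosis genes and 51.6% for the m6A genes. SUMO pathway genes, at 30.6%, lay within the random lists. Autophagy and mTOR genes were the 1 list below them, at 21.7% against a median of 35.5% (percentile 2.46), close to the limit. The random lists were not matched on RNA abundance. Among the 12 lists, wild-type clusters without a knockout counterpart ranged widely. They made up 0% for mitochondrially encoded transcripts and small structural RNAs and 16.25% for ribosomal protein genes. For the m6A genes it was 40.6% and for cell cycle and mitosis genes 44.6%. Whether a high share marks RNAs found in every list, rather than RBM33 contacts in particular, was not tested.

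Over all genes, 33.5% (33.0 to 34.0) of wild-type ALKBH5 clusters were overlapped by RBM33, against 18.9% with RBM33 clusters moved within gene and class. In turn 83.2% (82.6 to 83.8) of RBM33 clusters were overlapped by wild-type ALKBH5. Of genes with RBM33 clusters, 94.9% also had wild-type ALKBH5 clusters. No gene without ALKBH5 clusters had more than 2 RBM33 clusters. NDUFC1 and YAE1 had 2 each, and ABHD16A, ADCY5 and a 5_8S_rRNA copy had 1 each. The highest score in each list fell on the same place, chromosome 3, 96617186 to 96617996, at the RefSeq gene MTRNR2L12, a nuclear copy of mitochondrial ribosomal RNA, with the deposited score at 1872 for wild-type ALKBH5. Other places among the highest scores were at MTRNR2L8 for wild-type ALKBH5, in TUBA1A for knockout ALKBH5 and on the strand of MT-ND6 for RBM33.

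The third comparison asked whether the places also contacted by RBM33 were those missing without it. They were missing less often than the others. Of wild-type ALKBH5 clusters with an RBM33 cluster, 18.6% (17.9 to 19.3) had no knockout counterpart, against 53.1% (52.4 to 53.7) of those without, an odds ratio of 0.20 (0.19 to 0.21). FASN, with 39 of 50 clusters shared with RBM33, had 2 wild-type clusters without a knockout counterpart, and RYR2, with 6 of 27 shared, had 17. Several other genes named for their net loss, as RYR2 was, had many shared and many missing clusters. They were picked for missing clusters, so their counts do not test the pattern. The counts do not say which of the shared clusters were missing. CENPF had 10 of 22 shared and 19 missing, and MKI67 33 of 38 shared and 15 missing. ENSG00000280441 had 37 of 41 shared and 14 missing, and TOP2A 19 of 30 shared and 13 missing. Within genes the odds ratio was 0.21 (0.20 to 0.23). Without strata by gene, it was 0.33 (0.30 to 0.36) for the clusters of lowest score, 0.13 (0.11 to 0.14) for those of highest score and 0.30 (0.21 to 0.43) for intron clusters. Among genes, 7.27% of those with RBM33 clusters had no knockout cluster against 35.8% of those without, an odds ratio of 0.14 (0.12 to 0.16). Pooled over classes of clusters per gene it was 0.34 (0.30 to 0.39).

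Among clusters found in 1 ALKBH5 list but not the other, those of the wild-type list overlapped RBM33 more often. The share was 15.0% (14.4 to 15.6) of the 14664 in the wild-type list alone and 7.57% (7.06 to 8.10) of the 10112 in the knockout list alone. This comparison was chosen after the data were seen. Its odds ratio was 2.16 (1.98 to 2.35), and 1.65 (1.48 to 1.85) within genes. The RBM33 list and the wild-type ALKBH5 list come from cells of the same genotype, and both are named for control siRNA. The wild-type ALKBH5 list is also longer than the knockout list, and read depth is unknown.

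**Figure D4:**
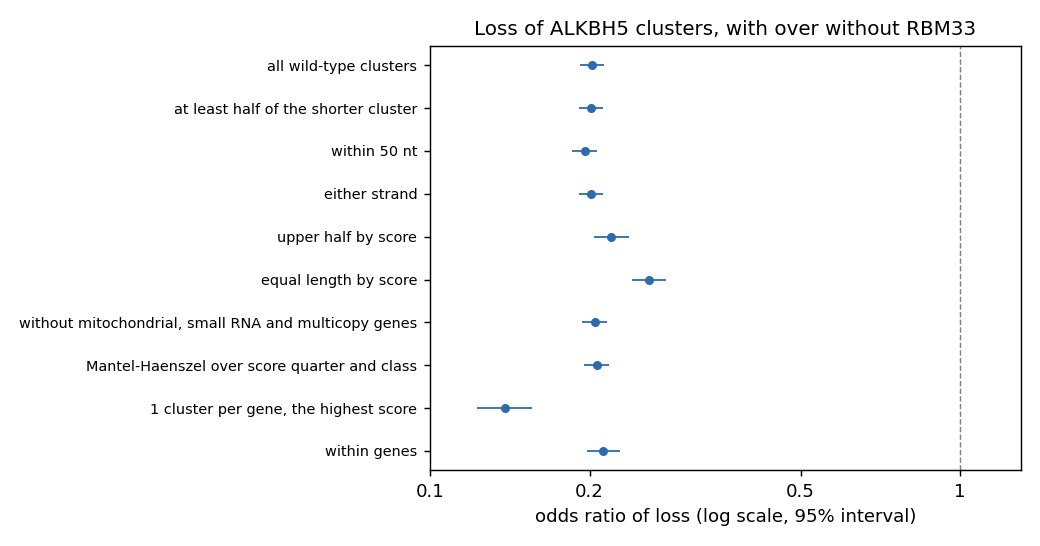
Odds ratio of loss from the knockout list for wild-type ALKBH5 clusters with over without an RBM33 cluster (x axis, log scale, bars are 95% intervals), for all clusters, for other choices of overlap and list, and pooled over strata. These 10 values lie between 0.14 and 0.26.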

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

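The comparison by exons, the within-gene odds ratio, motif density by exon, the ratio of summed clusters, the fixed lists and the small RNA share at equal length and the net clusters of named genes under other choices were tests chosen after the data were seen. No paired analysis was possible because the replicates were merged into 1 list per group, so the replicate block and leaving out a replicate were not run, nor was a ratio of per-cluster counts, which needs counts. The odds ratio of cluster loss stayed below 1 under 9 alternatives (0.14 to 0.26), and that of gene loss under 5 (0.13 to 0.34). The share of wild-type ALKBH5 clusters overlapped by the knockout list was 61.2% within 50 nt, 39.7% in the upper part of each list by score and 40.9% with lists of equal length. For overlap by RBM33 these were 35.7%, 22.4% and 31.0%, and 32.8% without mitochondrial, small RNA and multicopy genes. The share of genes kept was 78.3% with at least 2 clusters, 73.0% in the upper part by score and 73.2% at equal length. The coding share was 72.6% with 3' UTR ranked first, 75.3% in the upper part by score and 83.0% on either strand, and the 3' UTR share was 11.8%, 10.3% and 6.50%. The knockout 3' UTR share was lower under each of these 3 choices (-1.39 to -0.93 points). The RBM33 minus wild-type ALKBH5 difference in small RNA share was no longer apart from 0 at equal length (0.19 points). It was 0.93 points in the upper part of each list by score. Near the stop codon, with a window of 400 nt, the observed share over the expected one was 1.02 for wild-type ALKBH5, the opposite side of 1 from 200 nt, and 1.00 for knockout ALKBH5, no longer apart from 1. DRACH stayed above the shuffled share in all 3 lists under each choice. By summed clusters 1 fixed list lay outside the middle 95%. The SUMO list did not by summed clusters (24.0) or in lists limited by score (11.04 in the upper part, 16.5 at equal length), while SR proteins (1.02) and heat shock genes (2.48) did in the upper part and ribosomal protein genes (99.4) at equal length. Cell cycle and mitosis genes stayed outside in all 4 alternatives (0.01 to 0.65). The net difference of the 20 named genes changed with the score limit: in the 40 values by score or at equal length, 31 moved by over 1.5 times and that of ENSG00000280441 turned (-1), against 1 of 80 that moved under the other choices. Both score limits shorten the lists, so smaller net numbers follow in part from that alone. The cause was not tested for any of these. Depth is unknown, so a missing cluster cannot be told from a place with too few reads.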

Other observations

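The odds ratio of loss within genes, the test of a dependence on RBM33, the comparison of clusters in 1 ALKBH5 list alone and the comparison without CENPF were tests chosen after the result was seen. RNA classes differed in how often ALKBH5 clusters were in 1 list alone, in both directions. Of wild-type clusters in snRNA genes, 12.1% (3.40 to 28.2) had no knockout counterpart, of those in misc_RNA genes 12.8% (4.30 to 27.4), of those in pseudogenes 32.5% (30.0 to 35.1) and of those in protein-coding genes 42.0% (41.5 to 42.6). Of knockout clusters, 14.7%, 19.0%, 24.5% and 33.3% in the same order had no wild-type counterpart, so this is not particular to the knockout. For lncRNA genes the shares were 39.3% (35.7 to 42.9) and 36.5% (33.0 to 40.3), and for snoRNA or scaRNA genes 36.1% (25.1 to 48.3) and 19.6% (10.2 to 32.4), so noncoding classes did not all go the same way. RBM33 overlapped 84.8% of the snRNA clusters and 32.6% of the protein-coding ones. Lost coding clusters had a median GC content of 48.5%, kept ones 50.5% and those of the knockout list alone 51.2%. Internal coding exons of at least 500 nt were covered to 19.0% by the wild-type ALKBH5 list and to 15.0% by the knockout list, and those of 200 nt or less to 27.5% and 26.8%.

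Wild-type ALKBH5 clusters overlapped by RBM33 were missing from the knockout list less often than the others (odds ratio 0.20). Differences in transcript abundance between genes cannot be the whole cause, since the odds ratio within genes was 0.21. Places that are easy to detect turning up in every list may account for it: the mirror odds ratio, for knockout clusters missing from the wild-type list, was 0.093, below 1 as this predicts. It was 2.18 times lower than the first, and 1.55 times within genes, outside the 1.5 times set beforehand but close to it within genes, so the question stays open. The odds ratio of 0.20, and 0.21 within genes, met the criterion first written against a dependence of ALKBH5 on RBM33. That criterion was widened after the clusters in 1 ALKBH5 list alone had been compared. The odds ratio does not decide on a dependence, since detection alone brought it below 1 in simulated lists (0.37). The settings of that simulation were not fitted to these lists, so the size of 0.37 cannot be set against 0.20. Its mirror value was also 0.37, but its model makes the first and the mirror value equal by design. It therefore cannot say whether detection alone could give the gap between 0.20 and 0.093. The gap between the first and the mirror value is the same asymmetry as the higher RBM33 share among clusters of the wild-type list alone. A dependence and the shared genotype of the wild-type lists both stay open for it. So do differences between the ALKBH5 lists, which were not tested for it. The wild-type list is longer, with 35306 clusters against 30726, and depth is unknown. Median GC of coding clusters was 48.5% in the wild-type list alone and 51.2% in the knockout list alone. It was 48.7% in wild-type clusters with RBM33 and 50.4% in those without.

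Cell cycle and mitosis genes had fewer clusters in the knockout list than in the wild-type list. GC content of the clusters did not account for it, as the list stayed at percentile 0.17 among lists matched on GC. The length of the longest exon of any kind did not either (percentile 0.01 among lists matched on it). That exon can be untranslated, so this match cannot exclude a part of long internal coding exons. Those of at least 500 nt were covered to 15.0% by the knockout list and 19.0% by the wild-type list. Without CENPF the percentile was 1.14 by summed clusters and 1.44 by the median, so this 1 gene did not decide it. Much of the difference in summed clusters also came from MKI67 (38 and 24), TOP2A (30 and 19) and CENPE (20 and 11). The list without these genes was not tested. Of all its members, 13 had fewer clusters in the knockout list, 3 had as many and 4 had more. Fewer such transcripts in the knockout cells, or a different share of dividing cells, was not tested, as no RNA abundance was used here. A loss of ALKBH5 contacts on these transcripts stays an untested hypothesis.

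The highest score of each list lay at MTRNR2L12, a nuclear copy of mitochondrial ribosomal RNA. Not all of the 3 highest scores per list lay in such copies, as TUBA1A coding sequence and the mitochondrial genome were among them. Reads of a near-identical parent sequence could add fixed T-to-C differences to the score. Of 1216 wild-type clusters with a score of at least 100, outside the mitochondrial genome and the Y chromosome, 43.0% (40.2 to 45.8) had such a difference from their best match in another transcript, against 8.63% (7.12 to 10.4) of as many random clusters of lower score. A match of any kind was found for 52.2% and 20.6%, so the majority set beforehand was reached for any match but not for matches with such a difference. The number of differences rose with the score (Spearman rho 0.32, 0.26 to 0.37), short of the 0.5 set beforehand, so this explanation is open for the scores as a whole. Cluster width was not matched in these comparisons. Wider clusters can hold more such differences and, if the score is a sum over positions, a higher score.

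3' UTR sequence was covered 0.14 times (0.13 to 0.15) as much as coding sequence by wild-type ALKBH5, 0.14 times by knockout ALKBH5 and 0.10 times by RBM33. A loss of clusters in long exons cannot be the whole cause. Internal coding exons of at least 500 nt were covered 0.69 (0.62 to 0.77), 0.56 (0.50 to 0.63) and 0.76 (0.63 to 0.90) times as much as those of 200 nt or less in the same order of lists, all above the 0.33 set beforehand as needed. The 0.67 set beforehand to exclude it was not passed by more than the spread in any list, and the exclusion rests on the gap to the 3' UTR values, a rule chosen after the values were seen. Coding exons of at least 1000 nt, with a median length above that of the 3' UTRs, were covered 0.65 (0.54 to 0.77), 0.48 (0.38 to 0.58) and 0.78 (0.60 to 0.97) times as much. A smaller part of long exons in it stays open. 3' UTRs longer in the annotation than in the cells stay open too. The first 200 nt of 3' UTR were covered 0.65 (0.62 to 0.68), 0.69 (0.66 to 0.73) and 0.47 (0.43 to 0.51) times as much as the last 200 nt of coding sequence in the same exons, all below the 0.8 set beforehand as needed, but none below the 0.5 set to exclude it by more than the spread. No biological explanation was tested for this.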
